A study of Mus musculus with 18 samples.

How the data were processed

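RNA of splenic B cells was measured on 18 one-colour Cy5 arrays, 9 with gene probes and 9 with probes for mature miRNAs; which kind an array is was read from its probes. Each kind holds 3 arrays of founder line 9 (Tg9), 3 of founder line 79 (Tg79) and 3 of wild-type mice (WT). Both kinds carry the same titles, and the labels do not state that arrays of one title come from the same mouse, so no value was paired across kinds. Per the labels, B cells were isolated from the spleen with magnetic beads, total RNA was taken with Trizol, and amino allyl aRNA made from 1 µg of it was labelled with Cy5. The labels repeat this for the miRNA arrays.

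The deposited scanner files hold the median pixel intensity of each spot, with no normalization. A deposited background column rises with the spot itself (r on the log2 scale 0.892 to 0.964 on mRNA arrays and 0.982 to 0.995 on miRNA arrays, across spots, which are not independent replicates). It was therefore not subtracted, except in an alternative. The deposited series tables hold the authors' processed values on the log2 scale, with dim probes empty and columns centred on a common median, 5.5 for mRNA and 4.457 to 4.496 for miRNA arrays. How the authors made them is not given in the sources used here. In the miRNA table read here each value stands 5 rows away from the probe it belongs to; whether this arose in the deposit or later is not known. Spearman's rho with the scanner values of the same array, across probes, lay between 0.1415 and 0.1707 under the identifiers as given and was 1 after they were moved by 5 rows. The authors' miRNA values were used, in an alternative, with the identifiers moved.

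Values were computed from the scanner files in R 4.3.3 with limma 3.58.1. Spot intensities were corrected with normexp and an offset of 50 from the foreground alone, taken to log2, averaged per probe and quantile normalized within each kind of array. A probe was tested if it lay above the 95th percentile of the negative control spots (96 on an mRNA array and 24 on a miRNA array) on at least 3 of 9 arrays. This kept 18524 of 23473 mRNA probes and 501 of 1265 miRNA probes, of which 15823 and 282 were above that limit on all 9 arrays. Spots with a quality mark were left out; they touched 7 mRNA probes and 1 miRNA probe. Of the miRNA probes, 13 carry more than 1 name. The share of probes above the limit was 71.3% to 78.5% on mRNA arrays and 24.4% to 42.6% on miRNA arrays. Arrays give no count of molecules, and their number limits the precision.

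For each kind of array 1 limma model held the mean of each of the 3 groups, with empirical Bayes moderation, and gave transgenic (mean of both lines) against wild type, each line against wild type, and Tg79 against Tg9. Tests were two-sided, with Benjamini-Hochberg adjustment over all probes tested and a call at an adjusted p under 0.05. The replicate numbers were not used to pair arrays. Levels of a miRNA list are the mean log2 intensity over its tested members on each array, compared by an exact two-sided permutation of the array labels. There are 84 splits of 6 against 3, with a smallest p of 0.012, and 3 arrays against 3 cannot go below 0.10. The groups, comparisons, model, lists and the level of the miR-17~92 cluster were chosen before the data were examined. The levels of the other 5 lists, counts of probes without overlap, array quality weights, normexp with the background column and leaving out the arrays labelled Tg9-2 and Tg9-3 together were chosen after seeing the data. The miRNA arrays labelled Tg9-2 and Tg9-3 had a low cluster level, so miRNA results without them lean towards a larger difference.

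The rule for named miRNAs takes every measured arm of the miR-17~92, miR-106a-363 and miR-106b~25 clusters, the 8 largest changes each way past the threshold, and of each list up to 4 members with the smallest p for transgenic against wild type. Any other miRNA, and any mRNA probe, named in the text was chosen after its values were seen. The files do not pair the mRNA probe identifiers with gene names. The mRNA gene lists, the list of reported miR-17~92 targets, the seed-site test, which also needs 3' UTR sequences, and the mean over all probes of a gene were therefore not analysed here.

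Alternatives were the authors' values, no background correction, scaling to the 75th percentile, cyclic loess, no filter, a filter on all 9 arrays, eBayes with trend and robust, a model of 2 groups, fits of only the groups compared, the replicate number as a block, the slide of the miRNA arrays as a factor or as a random block, and leaving out each array in turn. The model was tested on simulated data of the same size, with 1 draw per setting. Its noise was independent between probes and equal in spread in all groups. Real arrays can share variation across probes and differ in spread between groups, so these rates may not hold for them. With 200 of 18518 mRNA probes changed, it called 74% of 2-fold and 92% of 4-fold changes for transgenic against wild type and 64% and 89% for Tg79 against wild type, with 10 and 6 false calls. With 40 of 501 miRNA probes changed it called 85% and 100%, then 70% and 95%, with 1 and 3 false calls. With nothing changed it made 0 calls for Tg79 against wild type.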

Results

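The arrays measured mRNA and mature miRNAs in splenic B cells of mice that carry the miR-17~92 cluster, a precursor of several growth-promoting miRNAs, under the immunoglobulin Eμ enhancer and heavy-chain promoter. There were 2 founder lines, Tg9 and Tg79, and wild-type mice, with 3 arrays each for mRNA and 3 each for miRNA. On miRNA arrays the share of probes above background was 35.1% to 40.8% in wild type, 33% to 42.6% in Tg9 and 24.4% to 32.3% in Tg79. The miRNA arrays lie on 3 slides. The first holds the 3 Tg9 arrays and WT1, the second the 3 Tg79 arrays and WT2, and the third WT3.

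The transgene's own product was read first, as the mean log2 intensity over the 11 of 12 arms of the miR-17~92 cluster above background. Its level was 7.68, 7.98 and 7.70 on WT1, WT2 and WT3, and 9.35, 10.25 and 9.88 on the Tg79 arrays 1 to 3. In Tg9 it was 9.31 on Tg9-1, but 7.99 on the array labelled Tg9-2 and 8.02 on the array labelled Tg9-3, next to the highest wild-type array. The means were 7.79 ± 0.17 in wild type, 8.44 ± 0.75 in Tg9 and 9.83 ± 0.45 in Tg79 (SD, n = 3). On miR-17-5p alone, the wild-type arrays read 10.26, 10.57 and 10.34, Tg9-1 read 13.25, the array labelled Tg9-2 read 10.60 and the array labelled Tg9-3 read 10.86.

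**Figure D1:**
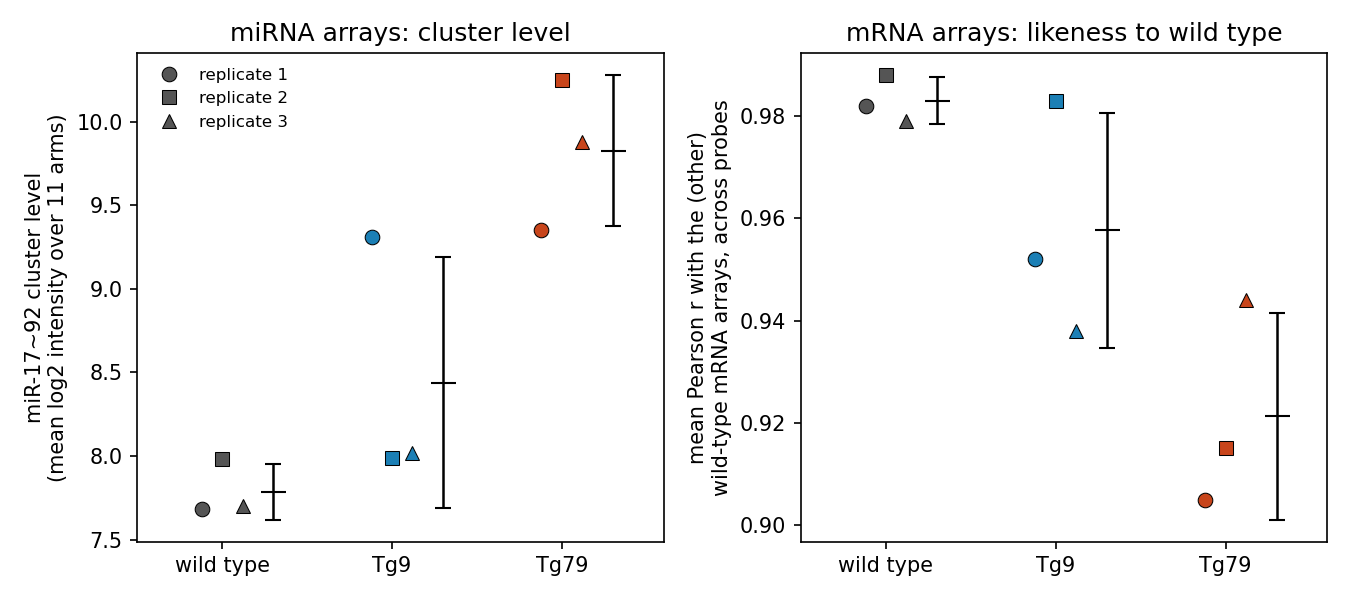
Left, the miR-17~92 cluster level (mean log2 intensity over 11 arms) of each miRNA array; right, the mean Pearson r across probes of each mRNA array with the (other) wild-type mRNA arrays; symbols are replicates, and the line and bar are the mean and SD of 3 arrays. Tg9-1 (9.31) lies by the Tg79 arrays on the left and the arrays labelled Tg9-2 (7.99) and Tg9-3 (8.02) by wild type, while on the right the array labelled Tg9-2 (0.983) lies among the wild-type arrays (0.979 to 0.988) and the array labelled Tg9-3 (0.938) does not.

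Transgenic against wild type compares the mean of both founder lines with wild type, so a change in a single line can carry it. The cluster level differed from wild type by 0.65 in Tg9 and by 2.04 in Tg79. The miR-17~92 cluster level was 9.13 ± 0.94 (SD, n = 6) on transgenic arrays and 7.79 ± 0.17 (n = 3) on wild-type arrays, a log2 difference of 1.35 (exact permutation p = 0.0476, 4 of 84 splits). All 6 transgenic arrays lay above all 3 wild-type arrays, with the array labelled Tg9-2 (7.99) next to WT2 (7.98). All 11 arms had a higher transgenic mean, from 0.46 log2 for miR-19b-1-5p to 2.08 ± 0.54 (SE) for miR-20a-5p. MiR-19b-1-5p was above background on only 5 of 9 arrays, so its size is uncertain. The 11 arms passed when adjusted over the list alone. Over all 501 miRNAs limma called 0, with 67 at an unadjusted p under 0.05 and a smallest adjusted p of 0.19; without Tg9-1 4 were called, without the arrays labelled Tg9-2 and Tg9-3 7, and with array weights 35. Arms of miR-106a-363, a paralogous cluster, were 0.84 higher in level (exact p = 0.0476), with 0 called over all miRNAs and 3, miR-106a-5p, miR-20b-5p and miR-18b-5p, adjusted over the list alone; that level difference missed an exact p of 0.05 in 9 of 18 alternatives, of which slide as a factor could not pass (highest 0.607, with the deposited background column). After Benjamini-Hochberg adjustment over the 6 lists both exact p-values become 0.143.

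The cluster difference passed an exact p of 0.05 only with some arrays and settings. Its exact p was 0.143 without WT1, 0.0714 without WT2, 0.107 without WT3, 0.0536 without the array labelled Tg9-2, the array labelled Tg9-3 or Tg79-3, and 0.0595 with 75th percentile scaling or with no filter. With slide as a factor the difference was 1.30, and its exact p of 0.0625 is the smallest that the 16 arrangements allow, so it could not pass. With the deposited background column, which follows the spot, the difference was 0.16 (exact p = 0.714).

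Tg79 against wild type asks what changed in this line. Limma called 23 of 501 miRNAs, 18 higher and 5 lower, 14 of them by at least 2-fold, with 123 at an unadjusted p under 0.05. Of the 11 tested miR-17~92 arms 9 rose, and 11 passed when adjusted over the list alone. Among them miR-20a-5p rose 7.58-fold (log2 2.92 ± 0.63 SE, adjusted p = 0.0477), miR-17-5p 7.52-fold (2.91 ± 0.63), miR-19a-3p 6.96-fold (2.80 ± 0.54), miR-92a-3p 5.44-fold (2.44 ± 0.36) and miR-18a-5p 5.07-fold (2.34 ± 0.40), with n = 3 in each group. Opposite strands of these hairpins, miR-17-3p (2.38), miR-20a-3p (1.77) and miR-18a-3p (0.89, above background on 1 wild-type array), rose as well. MiR-92a-1-5p was above background on 2 Tg79 arrays and no wild-type array. It was called higher (0.84 ± 0.16), but its size is uncertain. MiR-19b-3p had a log2 difference of 2.45 ± 0.59 (limma adjusted p = 0.0624). MiR-19b-1-5p, above background on 1 wild-type array and 2 Tg79 arrays, had one of 0.73, and neither was called.

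Some relatives of these miRNAs were called with them. From the miR-106a-363 cluster miR-20b-5p rose 8.77-fold (3.13 ± 0.48), miR-106a-5p 7.28-fold (2.86 ± 0.42) and miR-18b-5p 3.40-fold (1.76 ± 0.34), 3 of 6 tested arms. MiR-363-3p (0.06), miR-363-5p (-0.06) and miR-92a-2-5p (-0.05) of the same cluster were not called. MiR-92b-3p rose 5.33-fold (2.41 ± 0.39). From the miR-106b~25 cluster miR-93-5p rose 2.06-fold (1.05 ± 0.21, adjusted p = 0.0449), 1 of 5 tested arms, while miR-106b-5p (0.16), miR-106b-3p (0.28), miR-25-3p (-0.01) and miR-25-5p were not called; 2 arms passed adjusted over the list alone. The level of the miR-106b~25 arms differed by 0.30 (exact p = 0.20), and by -0.25 with the authors' values, which cover 4 arms. Relative to the median of all tested miRNAs it was higher by 0.33 here, by 0.58 with the authors' values and by only 0.05 with 75th percentile scaling.

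Outside these clusters miR-181b-5p, a miRNA of lymphocyte development, rose 2.21-fold (1.14 ± 0.22, adjusted p = 0.0387). Its family member miR-181d-5p (0.68, above background on 1 wild-type array), with miR-1943-3p (0.39) and miR-21a-3p, at least 1.29-fold higher, also rose; these 3 were named after their values were seen. The 5 that fell were miR-6240 (log2 -2.33 ± 0.40), miR-3102-5p (-0.81), miR-6244 (-0.49), miR-3105-5p, at least 1.48-fold lower, and miR-135a-2-3p, at least 1.05-fold lower. The last 2 were above background on no Tg79 array. The folds given as at least a value leave out the spread between arrays. MiR-135a-2-3p turned to 0.28 with 75th percentile scaling, still below the median of all tested miRNAs there (0.48).

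**Figure D2:**
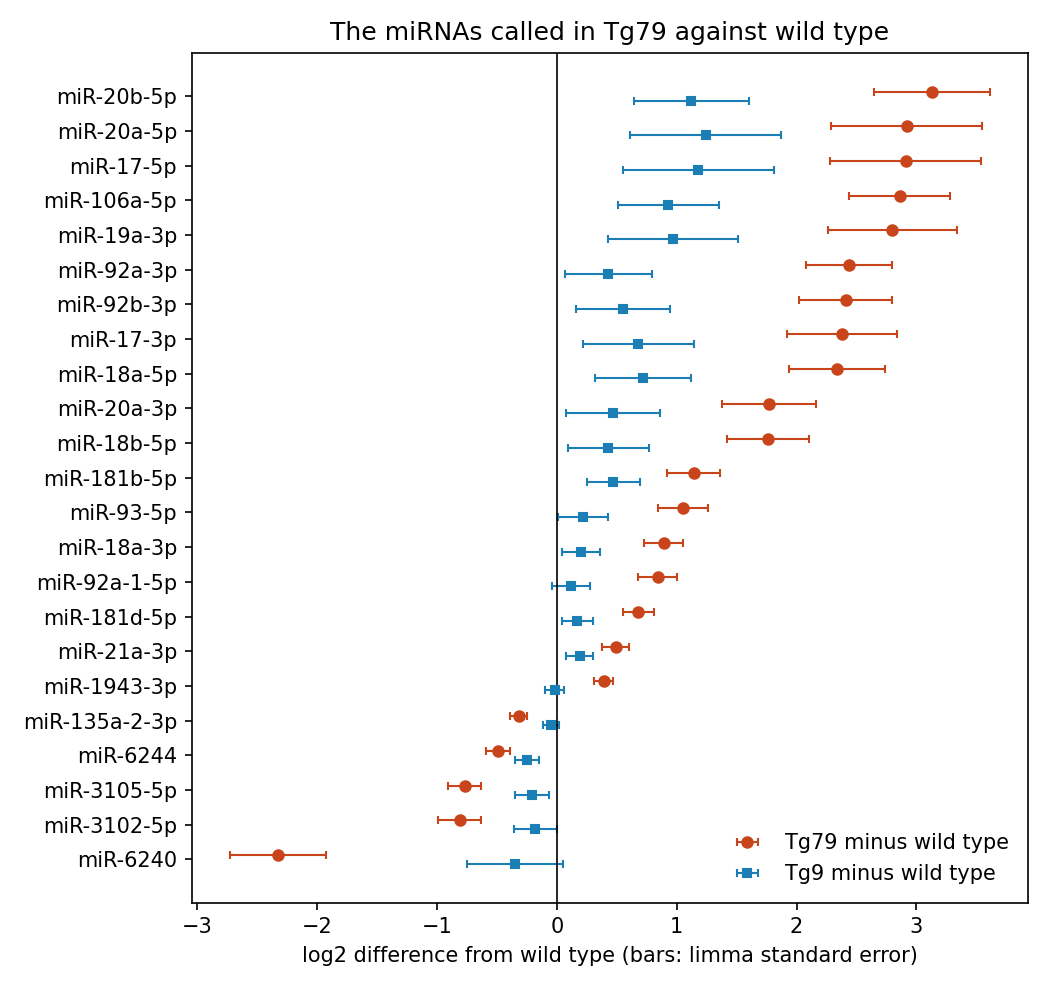
Log2 difference from wild type (horizontal axis) of the 23 miRNAs called in Tg79, for Tg79 (circles) and Tg9 (squares), with limma standard errors as bars. MiR-20b-5p is 3.13 higher in Tg79 and 1.12 in Tg9, and miR-6240 is at -2.33 and -0.35.

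These calls rest on few arrays. Without the array labelled Tg9-3, Tg79-2, WT1 or WT3, with no filter, with the background column, with the replicate number as a block or with slide as a factor 0 were called, 11 without Tg79-1 and 9 without WT2, while miR-17-5p stayed between 2.73 and 3.06 with 1 array left out and was 2.73 with slide as a factor. The background column follows the spot, so taking it away removes bright miRNA signal. With that column the sizes turned, miR-17-5p to -0.18, miR-92a-3p to -2.36, miR-106a-5p to -1.51, miR-181b-5p to -0.02 and miR-6240 to 0.70. The cluster level of Tg79 against wild type turned to -0.14. Within slides the Tg79 cluster level lay 1.84 above WT2 (1.37 to 2.27), against 2.04 over all wild-type arrays (exact p = 0.10, the smallest possible for 3 against 3). The median change of all tested miRNAs was -0.04 here but 0.48 with 75th percentile scaling and -0.84 with the authors' values, where 166 rose and 19 fell, and 16 rose and 92 fell, in turn. Relative to that median the cluster level was higher by 2.08, 1.89 and 3.12, the last over 8 of the 11 arms.

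Tg9 against wild type gave smaller differences, with the 3 arrays apart. Limma called 0 miRNAs, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.99. MiR-20a-5p had a log2 difference of 1.24 ± 0.63 (SE), miR-17-5p 1.18 ± 0.63, miR-20b-5p 1.12 ± 0.48 and miR-19a-3p 0.97 ± 0.54. On Tg9-1 miR-20a-5p read 12.91 against 9.91 to 10.26 in wild type, while the array labelled Tg9-2 read 10.39 and the array labelled Tg9-3 read 10.52. The cluster level differed by 0.65 (exact p = 0.10, the smallest possible), by 0.22 to 0.88 with 1 array left out (exact p up to 0.40) and, within the slide shared with WT1, by 0.76 (0.31 to 1.63). Without the arrays labelled Tg9-2 and Tg9-3, where the lone Tg9 array is assumed to vary like the other groups, 3 miRNAs were called.

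Tg79 against Tg9 tests whether the lines differ. Limma called 0 miRNAs, with 77 at an unadjusted p under 0.05 and a smallest adjusted p of 0.156. The cluster level was 1.39 higher in Tg79 (exact p = 0.10, the smallest possible), and all 11 arms passed adjusted over the list alone. That level difference turned to -0.59 with the background column, which follows the spot. MiR-92a-3p had a log2 difference of 2.01 ± 0.36 and miR-20b-5p one of 2.01 ± 0.48. Each line sits on its own slide. Counts in other settings point opposite ways. With the authors' values, where the median of all tested miRNAs was -0.56, 23 were called, all lower in Tg79. With 75th percentile scaling, where that median was 0.41, 9 were called, 8 of them higher. These 2 directions go with the shift of all miRNAs. Slide as a random block gave 34, 23 higher and 11 lower. Its estimated correlation within slides was negative (-0.14), which slide differences cannot give. These 34 calls therefore do not correct for the slide. Without Tg9-1 8 were called, all higher, and without Tg79-3 2, 1 each way.

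Of the let-7 family, miRNAs of differentiated cells, 0 of 9 were called in any comparison and 0 adjusted over the list alone. The level in Tg79 was 9.82 ± 0.19 against 10.21 ± 0.29 in wild type (difference -0.39, exact p = 0.10). This difference was 0.33 with the background column, which follows the spot, and -1.14 with the authors' values, which cover 7 members. Relative to the median of all tested miRNAs it was -0.35 here, -0.3 with the authors' values and -0.8 with 75th percentile scaling. For transgenic against wild type let-7i-5p differed by -0.48, let-7g-5p by -0.38, let-7f-5p by -0.34 and let-7a-5p by -0.24, and the level by -0.24 (exact p = 0.429). Without the array labelled Tg9-2, which had the highest let-7 level (10.81), that difference was -0.41 (exact p = 0.0179). The level in Tg9 differed from wild type by -0.09, by 0.01 with cyclic loess, 0.02 with the authors' values and -0.44 to 0.14 with 1 array left out.

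Of 17 lymphocyte miRNAs 1 was called in Tg79, miR-181b-5p, over all miRNAs and adjusted over the list alone. For transgenic against wild type miR-181b-5p differed by 0.81 ± 0.19, miR-21a-5p by 1.07 ± 0.30 and miR-142-3p, a miRNA of blood cells, by -0.74 ± 0.27, none called. MiR-34a-5p, a p53-regulated miRNA, differed by 0.54 ± 0.21 and was not called. It was above background on no wild-type array, 3 Tg9 arrays and 2 Tg79 arrays, so its size is uncertain. MiR-21a-5p read 11.83, 10.83 and 11.74 on the arrays labelled Tg9-1, Tg9-2 and Tg9-3 and 10.26 to 10.86 in wild type. In Tg79 miR-150-5p, a miRNA of mature lymphocytes, had a mean of 10.62 ± 1.63 against 12.62 ± 0.44 in wild type, miR-29a-3p 10.77 ± 0.88 against 12.40 ± 0.51, and miR-155-5p, a miRNA of activated B cells, 9.65 ± 1.40 against 8.12 ± 0.19. These 3 were named after their values were seen and were not called (limma adjusted p 0.175, 0.127 and 0.179). The list level differed by -0.42 in Tg79 (exact p = 0.10). There it differed by 0.70 with the background column, which follows the spot, and by -1.01 with the authors' values, which cover 16 members. Relative to the median of all tested miRNAs the Tg79 difference was -0.38 here, -0.17 with the authors' values and -0.79 with 75th percentile scaling. In Tg9 the list level differed by 0.01, by -0.05 with 75th percentile scaling, 0.22 with the authors' values, 0.62 with the background column and -0.12 to 0.18 with 1 array left out.

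**Figure D3:**
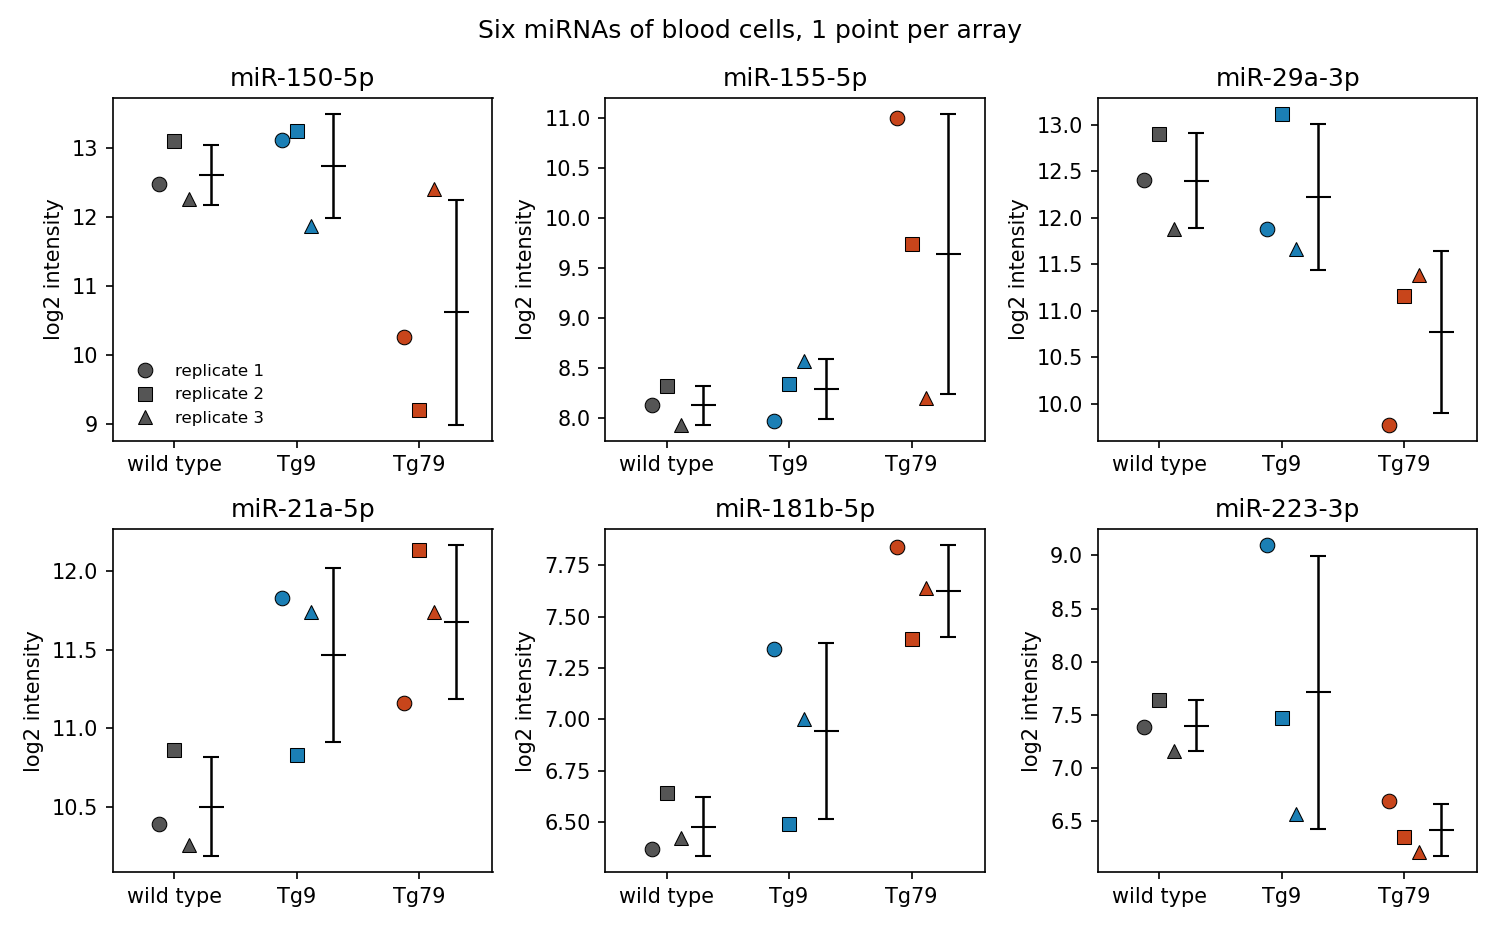
Log2 intensity of 6 miRNAs of blood cells on each miRNA array, with the mean and SD of 3 arrays, chosen after their values were seen. MiR-150-5p reads 10.26, 9.20 and 12.41 on the Tg79 arrays against 12.27 to 13.11 in wild type, and miR-223-3p reads 9.10 on Tg9-1 against 7.16 to 7.64 in wild type; only miR-181b-5p was called in Tg79.

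MiRNAs of myeloid, erythroid and endothelial cells, other cells that a B cell isolate can hold, did not pass. Of the 10 listed 6 were tested and 0 called, also adjusted over the list alone. Among these miR-126-3p, miR-143-3p, miR-125b-5p and miR-145a-5p were above background on 8, 7, 5 and 5 of 9 arrays. The list level therefore had little room to move, and a change in such cells is not excluded. MiR-223-3p, above background on all 9, read 9.10 on Tg9-1 and 6.21 to 6.69 in Tg79, against 7.16 to 7.64 in wild type. The level was 6.48 ± 0.06 in wild type, 6.66 ± 0.20 in Tg9 and 6.54 ± 0.34 in Tg79 (exact p = 0.20 and 0.70). MiR-126-3p of endothelium differed by 0.28 for transgenic against wild type, miR-451a of red cells by 0.47, miR-143-3p by 0.14 and miR-125b-5p by 0.09. The Tg79 difference in level was 0.07, but -0.82 with the authors' values and 0.55 with 75th percentile scaling (exact p = 0.10), each close to the median of all miRNAs there.

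On the mRNA arrays, transgenic against wild type gave 0 calls by limma over 18524 probes, with 4777 (25.8%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.06. At 3158 probes (17%) all 6 transgenic arrays lay on one side of all 3 wild-type arrays, 1417 higher and 1741 lower, where chance gives 2.4%; the count was 1446 with the background column and 3302 to 5034 with 1 array left out, where chance gives more. The array labelled Tg9-2 lay nearest to wild type: without it 1781 were called, and without Tg79-3 958. Without the arrays labelled Tg9-2 and Tg9-3 540 were called, with 75th percentile scaling 211, with trend and robust 31 and with array weights 4413.

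In Tg79 against wild type limma called 157 mRNA probes, 48 higher and 109 lower, 81 by at least 2-fold, with 4953 at an unadjusted p under 0.05. Probe M200002097 rose by 2.77 ± 0.45 log2 (SE, adjusted p = 0.0497) and M400010804 by 2.20 ± 0.21. M300005207 fell by about 5 log2, a size that is uncertain because the probe was above background on only 2 of 3 Tg79 arrays, and M300012030 fell by 2.31 ± 0.13 (adjusted p = 0.00463). The count was 0 without WT2 or WT3, 1 without WT1, Tg9-1 or Tg79-2, 6 without Tg79-1, 605 without the array labelled Tg9-3, 1313 without the array labelled Tg9-2 and 1622 without Tg79-3. It was 1 with cyclic loess, with no filter or with the replicate number as a block, and 521, with 268 higher and 253 lower, with 75th percentile scaling.

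In Tg9 against wild type limma called 0 mRNA probes, with 3023 at an unadjusted p under 0.05 and a smallest adjusted p of 0.229. The Tg9 arrays lay apart here too. At 157 probes chosen from the Tg79 arrays and 2 wild-type arrays, with the wild-type array left over as the comparison, Tg9-1 showed a median 67.2% to 71.6% of the Tg79 change, the array labelled Tg9-3 79.3% to 82% and the array labelled Tg9-2 7.4% to 14.2%, against -1.6% to 8.1% for the wild-type arrays left over. This comparison was chosen after the data were seen. Without the array labelled Tg9-2 347 probes were called, and without the arrays labelled Tg9-2 and Tg9-3 61.

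**Figure D4:**
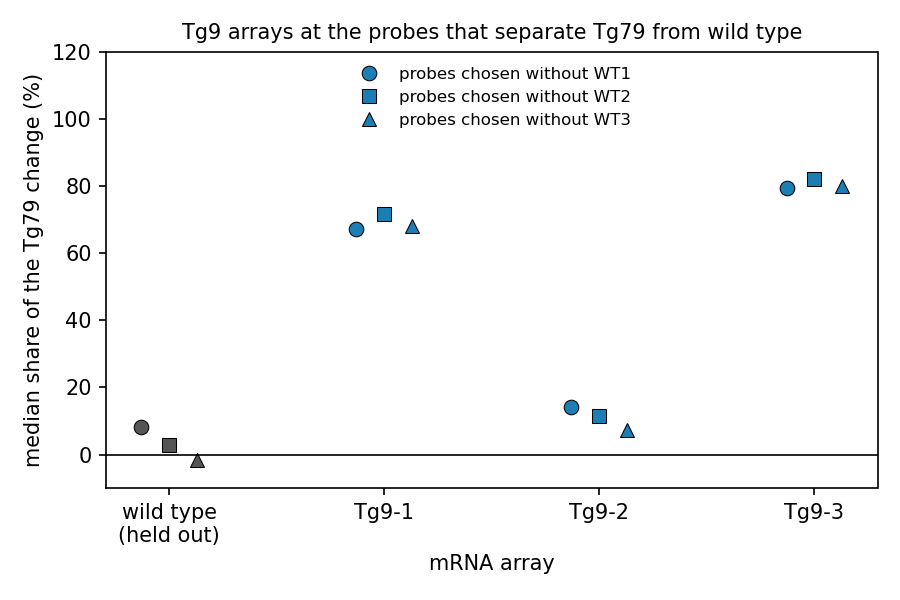
Median share of the Tg79 change (%, vertical axis) on each Tg9 mRNA array and on the wild-type array left out, at 157 probes chosen without that wild-type array; each symbol is 1 of the 3 choices. The array labelled Tg9-2 shows 7.4% to 14.2%, near the wild-type arrays, and Tg9-1 and the array labelled Tg9-3 show 67.2% to 82%.

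Between the lines limma called 1 mRNA probe, M300012030, at -1.84 ± 0.13 log2 for Tg79 against Tg9 (adjusted p = 0.0231), with 1440 at an unadjusted p under 0.05. It was not called with the authors' values, with only the 2 groups compared, with array weights or with the replicate number as a block, where the count was 0, nor with the background column or without Tg79-1, where other probes were called (1 and 2). The count was 0 without Tg79-2, the array labelled Tg9-2, WT1, WT2 or WT3, 131 without Tg79-3 and 5 without the array labelled Tg9-3.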

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

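All tests of explanations and of other splits of the arrays were chosen after the result they bear on was seen. Of 66 levels compared over the 6 transgenic arrays, 6 had 1 array far from the others, where chance gives about 1 in 20 within a single group. The arrays come from 2 lines and the levels are not independent, since the let-7 level holds let-7a-5p and let-7d-5p. That rate therefore does not apply here. The array labelled Tg9-2 was highest for the let-7 level (10.81, next 10.02), let-7a-5p (12.13, next 11.10) and let-7d-5p (11.88, next 11). Tg79-1 was lowest for miR-142-3p (9.36, next 10.26) and highest for miR-126-3p (6.90, next 6.36). Tg79-3 was lowest for miR-451a (6.75, next 7.66). A difference between the lines passed the limma test for mRNA probe M300012030, which was 1.84 lower in Tg79 (log2 -1.84).

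The arrays labelled Tg9-2 and Tg9-3 had a miR-17~92 level near wild type, unlike Tg9-1. A difference between slides cannot set Tg9-1 apart from the arrays labelled Tg9-2 and Tg9-3, since all Tg9 arrays lie on the same slide as WT1. Tg9-1 lay 1.63 above WT1, against a range of 0.31 among wild-type arrays. A swap with a wild-type array is argued against, since the highest wild-type array lay at -1.71 from the mean of Tg9-1 and the Tg79 arrays. Wild-type-like RNA on both arrays labelled Tg9-3 is argued against, since its mRNA array held at least 79.3% of the Tg79 change, with a mean r of 0.938 with the wild-type arrays, which correlate at 0.973 to 0.991 with each other. For the arrays labelled Tg9-2 it cannot be told apart from a weak response: its share was above that of the wild-type array left over in each of 3 choices of probes, which share arrays (14.2% and 8.1%, 11.5% and 2.8%, 7.4% and -1.6%), but the lowest lay inside the wild-type range, and the mean r was 0.983; r was compared first. A single wrong label or a swap with an outside sample, and transgene expression that varies between mice of line 9, may each account for what remains and were not tested.

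MiR-106a-5p, miR-20b-5p, miR-18b-5p and miR-92b-3p rose with the cluster in Tg79, by 1.76 to 3.13 log2. Their probes could bind the near-identical miR-17~92 products. Relatives with more base differences went both ways and do not decide this: miR-106b-5p and miR-25-3p changed by at most 0.16, while miR-93-5p rose by 1.05. A rise of the miR-106a-363 cluster itself is argued against, since its arms miR-363-5p (-0.06 ± 0.08 SE) and miR-92a-2-5p (-0.05 ± 0.14), above background on all 9 arrays, did not pass, while the opposite strands miR-17-3p (2.38) and miR-20a-3p (1.77) of miR-17~92, also above it on all 9, rose; miR-363-3p (0.06) was above background on only 2 of 3 Tg79 arrays. Base differences were taken from general knowledge of these miRNAs, not from probe sequences.

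The miR-17~92 level was higher in Tg79 than in wild type by 2.04. The difference was -0.14 with the background column, but that column follows the spot, so taking it away removes bright miRNA signal. The slide that holds the Tg79 arrays is argued against as the whole cause, since they lay 1.84 ± 0.45 (SD) above WT2 on that slide; the level was tested in place of the called miRNAs, which had been picked for this difference. The transgene, which the design names, is the biological explanation, and that reading remains a hypothesis here.

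Other splits of the arrays bear on the counts. With a real count of 0 every split gives at least as many, so such a count cannot tell whether chance is at work. For mRNA this holds for the 84 splits into 6 and 3 for transgenic against wild type in a fit of 2 groups (real 0). The highest other gave 741, from the split of Tg79-1, Tg79-2 and the array labelled Tg9-3 against the rest. Those 3 mRNA arrays had the lowest mean r with wild type (0.905, 0.915 and 0.938). Whether a further structure of the samples lies behind this split was not tested. At the 3158 mRNA probes without overlap, 1 of the 84 splits, the real one, gave as many (highest other 2640). That is the smallest share the 84 splits allow. Chance is therefore unlikely for that count but not excluded, since the count was chosen after seeing the data. With 1 array left out the count was 3302 to 5034, where the splits were not counted again. The limit of a real count of 0 holds for the 84 splits of the miRNA arrays too (highest other 24, Tg79 against the rest). Of those 84 splits 14 gave at least the real 19 miRNAs without overlap (3.8%, chance 2.4%, highest other 73), so chance cannot be excluded for that count, which was 19 to 90 with 1 array left out. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. For Tg79 against wild type 1 split gave as many, with 157 mRNA probes (highest other 0) and 23 miRNAs (highest other 0). For Tg9 against wild type it was 10 splits, with 0 mRNA probes (highest other 1) and 0 miRNAs (highest other 0), and for Tg79 against Tg9 5 splits with 1 mRNA probe (highest other 36) and 10 splits with 0 miRNAs (highest other 0).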

How the results depend on the processing

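Array weights, the background column and leaving out the arrays labelled Tg9-2 and Tg9-3 together were chosen after seeing the data; the cause was not tested except where given. Counts run transgenic against wild type, Tg9 against wild type, Tg79 against wild type and Tg79 against Tg9, and among these counts values that stayed within 1.5 times are left out. Similar counts need not hold the same probes. In Tg79 against wild type the authors' values called 202 mRNA probes, 78 of them among the main 157. The filter on all 9 arrays called 135, with 130 shared. Of the main 23 miRNAs, no background correction shared 23, cyclic loess 22, trend and robust 20, only 2 groups 17 and the filter on all 9 arrays 15. Without Tg79-3 29 miRNAs were called, with 13 shared. For mRNA (main 0, 0, 157, 1) the first count was 1 with no background correction, 211 with 75th percentile scaling, 1 with a filter on all 9 arrays, 31 with trend and robust, 15 with the background column, 4413 with array weights and 540 without the arrays labelled Tg9-2 and Tg9-3. The second was 6 with the background column and 61 without those arrays. The third was 401 with no background correction, 521 with 75th percentile scaling, 1 with cyclic loess, 1 with no filter, 738 with trend and robust, 927 with only 2 groups, 26 with the background column, 2723 with array weights and 931 without those arrays. The last was 0 with the authors' values, only 2 groups or array weights and 28 without those arrays. Leaving out 1 array gave 0 to 1781, 0 to 347, 0 to 1622 and 0 to 131. For miRNA (main 0, 0, 23, 0) the first was 35 with array weights and 7 without those arrays, and the second 3 without them. The third was 108 with the authors' values, 185 with 75th percentile scaling, 0 with no filter, 0 with the background column, 79 with array weights, 0 with slide as a factor and 39 with slide as a random block (consensus correlation -0.14). The last was 23 with the authors' values, 9 with 75th percentile scaling, 34 with slide as a random block and 1 without those arrays. Leaving out 1 array gave 0 to 4, 0 to 0, 0 to 29 and 0 to 8. The consensus correlation of the random block was negative, which slide differences cannot give, so its counts do not correct for slides. Probes without overlap of transgenic and wild type ran from 1446 to 5533 for mRNA (main 3158) and from 7 to 99 for miRNA (main 19), each lowest with the background column and highest without the arrays labelled Tg9-2 and Tg9-3; fewer arrays raise the share chance gives (2.4% with all 9). The cluster level for Tg9 against wild type (0.65) was 0.22 to 0.88 with 1 array left out and 1.53 without those arrays. The replicate numbers do not pair the samples: correlations of same-number arrays after removing group means ran from -0.25 to 0.12 for mRNA and -0.43 to 0.38 for miRNA, over 0.1 in 1 and 3 of 9 pairs, and a replicate block gave 0, 0, 1, 0 mRNA probes and 0, 0, 0, 0 miRNAs. The cluster level for transgenic against wild type (1.35) stayed positive throughout: 1.12 to 1.58 with 1 array left out (exact p 0.0357 to 0.143), 1.5 with 75th percentile scaling (exact p 0.0595), 1.24 with no filter (0.0595), 1.30 with slide as a factor (exact p 0.0625, the smallest its 16 arrangements allow) and 0.16 with the background column (exact p 0.714), where it turned to -0.14 for Tg79 against wild type and -0.59 for Tg79 against Tg9. That column read 0.86 to 1.11 times the spot for bright miRNA spots and 0.27 to 0.48 times for mRNA, so taking it away removes bright miRNA signal. With it miR-17-5p went to -0.18, miR-106a-5p to -1.51, miR-92a-3p to -2.36, miR-17-3p to -0.06, miR-18a-5p to -1.02, miR-92a-1-5p to -0.01, miR-93-5p to -0.41, miR-6240 to 0.70, miR-3102-5p to 0.75, miR-181b-5p to -0.02, miR-1943-3p and miR-21a-3p to -0.01 and miR-3105-5p and miR-181d-5p to 0.00; miR-135a-2-3p went to 0.28 with 75th percentile scaling. With 75th percentile scaling the median of all tested miRNAs was 0.48, so miR-135a-2-3p stayed below it. No other setting reversed the sign of any of the 23 miRNAs called in Tg79. MiRNAs that were not called were not run. The mean over the probes of a gene, the gene lists and the seed-site settings were not run, since the files do not pair probes with genes. Signal over background limits the miRNA arrays, with 650 of 1265 probes above it on no array.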

Other observations

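The tests here were chosen after the values were seen. On Tg9-1 miR-223-3p, a miRNA of myeloid cells, read 9.10, against 7.16 to 7.64 in wild type, while the array labelled Tg9-3 read 6.57 and the Tg79 arrays 6.69, 6.35 and 6.21 (Tg79 against wild type -0.98, limma adjusted p 0.32, not called). On Tg9-1 miR-451a read 8.05 against 6.97 to 7.65 and miR-126-3p 6.27 against 5.94 to 6.23.

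At the miRNAs called in Tg79, Tg9-1 lay beyond all wild-type arrays in the Tg79 direction for 21 of 23, the array labelled Tg9-2 for 10 and the array labelled Tg9-3 for 11. At the mRNA probes called in Tg79 the counts were 152, 124 and 151 of 157; since those miRNAs and probes were chosen with the same wild-type arrays, all 6 counts lean towards the Tg79 direction.

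The differences of both lines from wild type correlated across probes with r = 0.80 for mRNA and 0.77 for miRNA. Both share the 3 wild-type arrays, and 100 simulated data sets with no effect gave a mean r of 0.29 and 0.36. The covariance was 0.143 against 0.0136 simulated for mRNA and 0.121 against 0.0252 for miRNA. Probes are not independent replicates, and 3 wild-type arrays cannot be parted into 2 sets of 2. Variation that many probes share on the wild-type arrays could also raise r, so these values cannot part it from a common response.

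The authors' miRNA values, read under the identifiers as given, gave a miR-17~92 level difference for transgenic against wild type of -0.73 over 4 arms (exact p = 0.238), a miR-17-5p difference in Tg79 of -0.77 and 60 called miRNAs in Tg79. With the identifiers moved by 5 rows they gave 1.62 over 8 arms (exact p = 0.0476), 2.48 and 108. The reading as given was set aside as an alternative after these values were seen, because its values do not match the scanner files.

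The miRNA arrays also carry 31 probes named S-Probe, whose targets are not given in the sources used here. Of these 11 were above background on all 9 arrays, and 0 had all transgenic arrays above all wild-type arrays.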
